A study of Mus musculus with 12 samples.

How the data were processed

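RNA from left kidneys of wild type and Sprr2f knockout mice was sequenced at day 0 and day 5 of unilateral ureteral obstruction, with 50-base reads in 12 libraries of 2, 3, 4 and 3 samples per group. Per the submitters' processing notes, reads were aligned with STAR to GRCm38.p6, handled with SAMtools and counted to genes with HTSeq, without versions. The deposited values are CPM, although the file name calls them counts: every column has the same sum. Dividing each column by its smallest step recovered whole reads (100% of the 665652 values lay within 0.001 of a whole number), which gave 16567256 to 19398882 reads per library. A single read was thus 0.0515 to 0.0604 CPM. Of the 55471 gene identifiers, 55230 are in GENCODE M21, used for coordinates, and 241 are not.

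The test planned before the data were examined was the edgeR quasi-likelihood test on counts. Because the deposited unit is CPM, log2(CPM + 0.5) after TMM scaling was instead fitted with limma 3.58.1 (empirical Bayes with a trend) in R 4.3.3, and edgeR 4.0.16 on the recovered reads became an alternative. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 18093 genes holding 99.9% of reads. The 4 groups of genotype and day were fitted together in all 12 libraries, and p-values were adjusted by the Benjamini-Hochberg method, called at 0.05. The edgeR test called 4327 genes higher and 4130 lower for obstruction in wild type (limma 4440 and 4087), 5350 and 4482 in knockout (5328 and 4589), 0 and 3 for genotype at day 0 (0 and 3), 0 and 0 at day 5 (0 and 0), 1 and 0 for the interaction (1 and 0), and 1 and 1 for genotype averaged over both days (1 and 1).

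Gene lists were fixed with the design: 40 lists, of which 37 had at least 5 tested genes and were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry (directional and mixed) were alternatives. The lists cover the Sprr family and its neighbours, NRF2 targets, antioxidant enzymes, NADPH oxidase, tubular injury, nephron segments, podocytes, endothelium, matrix, myofibroblasts, TGF-beta, immune cell kinds, cytokines, interferon, complement, cell cycle, p53, energy metabolism, the mitochondrial genome, glycolysis, the unfolded protein response, immediate early genes, the circadian clock, sex chromosome and sex-dimorphic genes, urothelium, adipocytes, skeletal muscle and erythroid cells. The lists of adrenal (3 tested genes), pancreas (1) and replication-dependent histones (0) were not tested. The symbols of the histone list are older than those of the file; matched by gene identifier it was tested in 1 fit with these 37, a step added after the data had been seen.

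Genes named are the tested Sprr family, the 8 largest rises and 8 largest falls per comparison (adjusted p under 0.05, mean log2 CPM of at least 1, a symbol that is no predicted model, and no overlap between the libraries of the groups), up to 4 members per list with the smallest adjusted p, and all genes where fewer than 20 passed. Results for 1 gene are not reported here. Scaled CPM is CPM divided by the TMM factor. Sprr genes with few reads in a group were compared by reads per library size with exact binomial intervals at 95%, and against a floor of 3 reads. An exact permutation test was used for Sprr2f at day 5. The 50-base sequences of each Sprr transcript were compared with the transcripts of every other GENCODE M21 gene.

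The alternatives chosen in advance were DESeq2 1.42.0, limma-voom, edgeR with robust settings, RLE and upper-quartile factors, library size only, no filter, a stricter filter (CPM of 1 in 2 libraries, 16271 genes), mitochondrial genes left out, only the compared groups in the fit, a 1.5-fold threshold, and each library left out in turn. Chosen after the data had been seen were edgeR on the recovered reads, 0.1 and 1 CPM instead of 0.5, the sex-chromosome transcript pattern of each library as a covariate, the Sprr list without Sprr2f, only the 7 libraries with Y-linked transcripts, and only the 5 with Xist. Among the Y-linked libraries 3 groups hold 1 library each, so that fit compares single libraries at day 5 and takes its spread from the 4 knockout libraries at day 0. The covariate is 1 term, which takes the sex difference to be equal in all groups. All 4 knockout libraries at day 0 are Y-linked, so its size comes from the other groups. The difference can be unequal: wild type Cyp2j13 stood at 198 (Y-linked) and 0.786 (Xist) scaled CPM at day 0. At day 5 these were 89.6 (Y-linked) and 6.72 and 11.7 (Xist). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

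The limma test was tested on simulated data, with 100 genes changed 2-fold and 100 changed 4-fold at these group sizes. It recovered 52% and 73% for obstruction in wild type (17465 genes), 62% and 90% in knockout (17445 genes), 49% and 89% for genotype at day 0 (17403 genes) and 54% and 89% at day 5 (17487 genes). Of its calls, 5.30%, 3.80%, 8% and 2.72% were unchanged genes. Lists changed 2-fold were recovered (adjusted p = 1.58e-58 for proximal tubule, 2.57e-07 for neutrophil and 2.49e-45 for circadian genes), with 1 of 34, 1 of 36 and 0 of 36 other lists called. The simulated genes varied independently. In the real data the estimated correlation within lists was, for example, 0.259 for tubular injury and 0.556 for cell cycle genes. The simulation therefore cannot show how often lists of correlated genes are called falsely at the fixed correlation.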

Results

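RNA was sequenced from 12 left-kidney samples of mice in 4 groups. Wild type kidneys were taken at day 0 (n = 2) and at day 5 (n = 3) of unilateral ureteral obstruction (UUO), in which a clamp on the left ureter blocks the outflow of urine. Kidneys of mice lacking Sprr2f, which encodes a small proline-rich protein of the epidermal barrier family, were taken at day 0 (n = 4) and day 5 (n = 3). Each library held between 16567256 and 19398882 reads counted to genes. The labels do not say whether the day 0 kidneys were sham-operated or untouched, nor give the sex of each mouse. They do not say that replicates are more than separate samples, so the p-values measure the spread between these samples. Of 55471 annotated genes, 33465 had at least 1 read and 18093 were tested.

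Obstructed kidneys held a smaller share of mitochondrially encoded transcripts, 3.89% to 4.34% of reads at day 5 against 8.31% to 9.26% at day 0. The 10 most abundant genes of each library took 7.33% to 8.12% of reads at day 5 and 14.1% to 16.6% at day 0. Scaling factors (TMM) were 1.13 to 1.19 at day 5 and 0.795 to 0.897 at day 0. With library size alone the median gene moved up by a further 0.37 log2 units in wild type and 0.38 in knockout, and 81.1% and 82.3% of the called genes were higher at day 5, against 52.1% and 53.7% with these factors. Changes below are relative to the factors. Within groups, log2 values of replicate pairs correlated across genes with Pearson r = 0.977 to 0.993.

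Sprr2f (ENSMUSG00000050635, protein-coding, chromosome 3, 92365187 to 92366442, plus strand, GRCm38 with GENCODE M21) was nearly absent from kidneys at day 0 of both genotypes and abundant at day 5 in wild type alone. Its deposited CPM was 0.106 and 0 in wild type at day 0 (2 and 0 reads) and 27.1, 26.9 and 58.8 at day 5 (482, 447 and 1138 reads). Knockout kidneys held 0.262, 0.121, 0 and 0 CPM at day 0 (5, 2, 0 and 0 reads) and 0, 2.17 and 4.07 CPM at day 5 (0, 39 and 76 reads). Group means were 37.6 ± 18.4 CPM (SD, n = 3) in wild type and 2.08 ± 2.04 CPM (SD, n = 3) in knockout at day 5. Relative to depth, pooled wild type libraries held 718 times as many Sprr2f reads at day 5 as at day 0 (95% interval 198 to 5929) and 18.7 times as many as the knockout at day 5 (15.5 to 22.8). Intervals and floors here cover counting error only. An exact two-sided permutation test of the day 5 libraries gave p = 0.1, the smallest that the 10 splits of 3 against 3 allow. Of the 560 distinct 50-base sequences in the Sprr2f transcript, 4 also occur in another gene (0.714%, Sprr2e), so its reads could be told from those of its relatives.

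**Figure D1:**
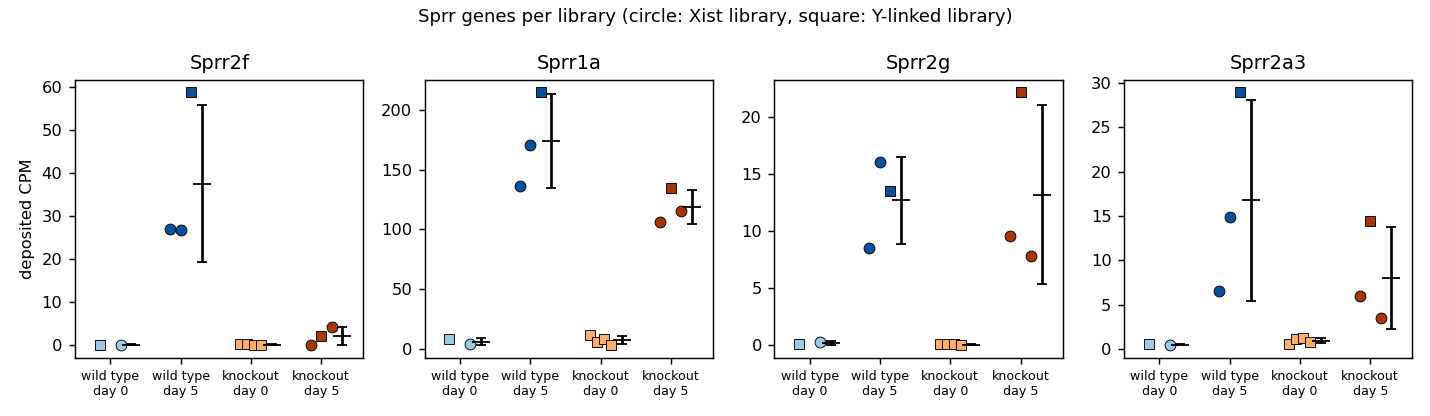
Deposited CPM of Sprr2f, Sprr1a, Sprr2g and Sprr2a3 in each of the 12 libraries, with circles for libraries holding Xist, squares for libraries holding Y-linked transcripts, and black marks for the group mean ± SD. Sprr2f reached 26.9 to 58.8 CPM in wild type and 0 to 4.07 CPM in knockout kidneys at day 5, while Sprr2g had means of 12.7 and 13.2 CPM.

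The Sprr2f difference between genotypes at day 5 was a log2 fold change of -4.14 ± 0.59 (SE), below every wild type library in all 3 knockout libraries, but its adjusted p over all genes was 0.152. With the sex-chromosome transcript pattern described below as a covariate the adjusted p was 0.0481, and over all alternatives it ran from 0.0262 to 1. During obstruction the transcript rose by 5.75 ± 0.66 log2 units in wild type (adjusted p = 1.54e-05) and by 1.49 ± 0.55 in knockout (adjusted p = 0.0362), values that depend on the 0.5 CPM added before the logarithm. The knockout rise, 21.4 times in pooled reads (95% interval 10.1 to 54.4), lost its call with limma-voom, with no filter, with a 1.5-fold threshold or with 0.1 CPM added. It also lost the call without knockout day 0 replicate 2, 3 or 4, and without knockout day 5 replicate 2 or 3 (log2 fold changes 1.23 and 0.86), and it was 2.36 without replicate 1. Among the other tested Sprr genes, Sprr1a rose by 4.42 ± 0.41 and 3.66 ± 0.35 log2 units in wild type and knockout, Sprr2g by 4.02 ± 0.38 and 4.30 ± 0.32, and Sprr2a3 by 3.50 ± 0.56 and 1.98 ± 0.47. Sprr2g had 6 and 3 reads at day 0 and 680 and 730 at day 5, ratios relative to depth of 78.7 (95% interval 36.0 to 215) and 317 (108 to 1541). Of the 6 wild type reads at day 0, 5 were in replicate 2, so the wild type ratio depends on that library. Sprr2a3 shares 61.1% of its 50-base sequences with other genes, among them Sprr2a1, Sprr2a2, Sprr2b and the pseudogene Rpl21-ps8. Sprr2h had 0, 2 and 1 reads in wild type and 2, 60 and 11 reads in knockout kidneys at day 5, and 0 in every day 0 library. Against a floor of 3 reads over the day 0 group, Sprr2h was at least 31.7-fold higher at day 5 in knockout, but at least 8.31-fold without replicate 2, which held 60 of the 73 reads. As a list of 5 tested genes the Sprr family rose in wild type (4 higher, 0 lower and 1 not called, median 4.02, adjusted p = 0.0414, adjusted p = 0.390 with an estimated correlation), a call that ended without either wild type day 0 library (adjusted p = 0.0543 and 0.0589). In knockout the list did not pass (5 higher, 0 lower and 0 not called, median 1.98, adjusted p = 0.0507, adjusted p = 0.439 with an estimated correlation), but it did with the sex-pattern covariate (median 2.76, adjusted p = 0.00407, and 0.162 with an estimated correlation). Its median was 3.66 with Sprr2h at its lower bound, or 3.06 with the bound without replicate 2. The 4 genes other than Sprr2f, tested in its place after the data had been seen, gave medians of 3.76 in wild type and 2.82 in knockout (adjusted p = 0.0612 and 0.0371, and 0.401 and 0.375 with an estimated correlation).

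The title of the series gives female mice, yet 7 of the 12 libraries held Y-linked transcripts. The summed CPM of Ddx3y, Uty, Kdm5d and Eif2s3y was 112 to 170 in those 7 and 0.281 to 0.979 in the other 5, which held 481 to 893 CPM of Xist against 0.329 to 2.11. The 7 were 1 of 2 wild type libraries at day 0, 1 of 3 at day 5, all 4 knockout libraries at day 0 and 1 of 3 at day 5. Between Y-linked and Xist libraries within groups, 1389 of 17493 tested autosomal genes differed (624 higher and 765 lower in Y-linked libraries), among them 15 of 15 genes of the sex-dimorphic renal list. Examples were the acyl-CoA synthetase gene Acsm3 (6.38 ± 0.15 log2 units), the organic anion transporter gene Slco1a1 (6.27 ± 0.28) and, in the other direction, the prolactin receptor gene Prlr (-3.85 ± 0.42). The share of Y-linked libraries therefore differed most in knockout against wild type at day 0 and in day 5 against day 0 in knockout, and less in wild type obstruction. Neither the sex chromosome list nor the sex-dimorphic list passed in wild type obstruction (medians -1.15 and -1.03, adjusted p = 0.734 and 0.281). In knockout obstruction their medians were -3.63 and -2.90 (adjusted p = 0.212 and 0.0923). With the sex pattern as a covariate the sex-dimorphic list was lower after obstruction in wild type (1 higher and 9 lower, median -0.95, adjusted p = 0.00169) and in knockout (3 higher and 10 lower, -1.47, 0.0111), and neither passed with an estimated correlation (adjusted p = 0.125 and 0.204).

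**Figure D2:**
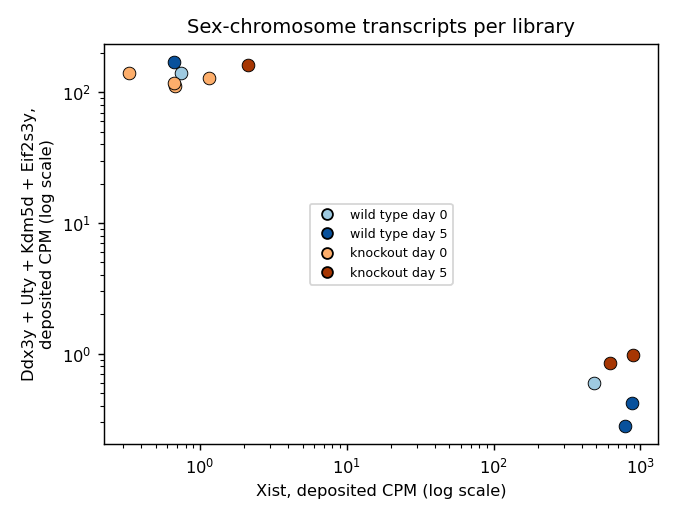
Xist against the summed Y-linked transcripts Ddx3y, Uty, Kdm5d and Eif2s3y in deposited CPM, both axes on a log scale, with 1 point per library coloured by group. The 7 libraries at the upper left hold 112 to 170 CPM of Y-linked transcripts, and the 5 at the lower right hold 481 to 893 CPM of Xist.

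The comparison of wild type kidneys at day 5 (n = 3) with day 0 (n = 2) shows what 5 days of obstruction did to the normal kidney. Tubular injury genes were among the most strongly raised. Havcr1, the injury receptor of tubule cells, went from 3.51 ± 3 to 841 ± 310 scaled CPM (SD), a log2 fold change of 7.89 ± 0.59 (SE). Krt20, a keratin, rose by 7.46 ± 0.54 and Lcn2, a secreted iron-carrier protein, by 6.35 ± 0.32. Pvalb, a calcium-binding protein of the distal convoluted tubule, fell from 40.3 ± 5.48 to 0.130 ± 0.109 scaled CPM (log2 fold change -6.02 ± 0.22), and Egf, made by the thick ascending limb and distal tubule, changed by -3.75 ± 0.53. At an adjusted p under 0.05, 4440 genes were higher and 4087 lower, 47.1% of those tested, of which 2278 and 1494 changed at least 2-fold.

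In knockout kidneys at day 5 (n = 3) against day 0 (n = 4), the comparison that asks how kidneys respond without Sprr2f, the leading genes moved in the same directions. Havcr1 changed by 7.35 ± 0.49 log2 units (from 3.12 ± 1.33 to 694 ± 574 scaled CPM), Krt20 by 6.57 ± 0.45, Lcn2 by 5.83 ± 0.26, Pvalb by -5.91 ± 0.18 and Egf by -3.17 ± 0.44. In all, 5328 genes were higher and 4589 lower (54.8%), 2111 and 1442 of them at least 2-fold. Across the 18093 genes, which are not independent replicates, the fold changes of both genotypes correlated with Pearson r = 0.904 and Spearman rho = 0.879. Genes called higher in both numbered 3843 and genes called lower in both 3466, where independent lists would share 1307 and 1037, and 7 were called in opposite directions. A further 1211 genes passed in wild type alone and 2601 in knockout alone, a split that is no test of a difference. Genes of the sex pattern stood among the largest falls in knockout: Slc7a13 (-6.52 ± 1.70), Slco1a1 (-6.50 ± 1.86), Acsm3 (-6.40 ± 1.87), Cyp4b1 (-5.00 ± 0.95) and Pzp (-4.43 ± 0.94) became -2.71, -2.32, -2.15, -2.94 and -2.35 with the sex-chromosome transcript pattern as a covariate. Slc7a13, Slco1a1 and Acsm3 lost their calls with DESeq2 and with robust edgeR (log2 fold changes with the latter -4.66, -4.22 and -4.10), and Acsm3 also without knockout day 5 replicate 1 (-5.44) or 3 (-5.42). Their adjusted p over all alternatives ran from 5.98e-06 to 0.113, 9.78e-05 to 0.153 and 7.56e-07 to 0.180.

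The group changes below give wild type first, and counts adjusted over the list alone where these differ from the counts over all genes. Tubular injury genes rose in both genotypes. In wild type there were 27 higher, 0 lower and 3 not called, 28 higher and 0 lower adjusted over the list alone (median 2.72, adjusted p = 1.15e-12, adjusted p = 0.111 with an estimated correlation). In knockout the tubular injury genes list had 29 higher, 0 lower and 1 not called (median 2.50, adjusted p = 2.65e-12, adjusted p = 0.123 with an estimated correlation). Spp1, which encodes osteopontin, rose by 3.71 ± 0.22 and 4.20 ± 0.18 log2 units, Clu, a secreted chaperone, by 2.89 ± 0.13 and 2.96 ± 0.11, and the developmental transcription factor gene Sox4 by 2.21 ± 0.10 and 2.15 ± 0.09. Timp1, a metalloproteinase inhibitor, rose by 6.71 ± 0.49 and 5.49 ± 0.41 and, outside the lists, Serpina10, a coagulation inhibitor, by 5.88 ± 0.29 and 5.64 ± 0.24, and Aoc1, a histamine-degrading oxidase, by 5.64 ± 0.27 and 5.26 ± 0.23. Urothelial genes also rose (11 higher, 0 lower and 3 not called, 13 higher and 0 lower adjusted over the list alone, median 1.97, adjusted p = 0.00370, adjusted p = 0.475 with an estimated correlation), the keratin genes Krt15 by 3.01 ± 0.49 and 2.22 ± 0.41 and Krt14 by 3.49 ± 0.64 and 2.51 ± 0.54. In knockout the urothelium list had 11 higher, 0 lower and 3 not called, 12 higher and 0 lower adjusted over the list alone (median 1.48, adjusted p = 0.0196, adjusted p = 0.572 with an estimated correlation). The knockout call on urothelium ended without knockout day 5 replicate 2 (adjusted p = 0.0559). Other genes of the epidermal differentiation complex, the chromosomal neighbours of the Sprr family, rose as a list in wild type (7 higher, 2 lower and 2 not called, 8 higher and 2 lower adjusted over the list alone, median 0.72, adjusted p = 0.0395, adjusted p = 0.390 with an estimated correlation) except without knockout day 0 replicate 2 (adjusted p = 0.0567). In knockout they did not pass (7 higher, 3 lower and 1 not called, median 0.73, adjusted p = 0.149, adjusted p = 0.509 with an estimated correlation), but they did with the sex-pattern covariate (median 0.79, adjusted p = 0.0257, and 0.243 with an estimated correlation). Among them, Ivl, an envelope protein of keratinocytes, rose by 4.22 ± 0.48 and 3.24 ± 0.40 and S100a6, a calcium-binding protein, by 3.51 ± 0.30 and 2.99 ± 0.25.

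Proximal tubule genes, which serve reabsorption, fell in both genotypes. In wild type they had 1 higher, 28 lower and 1 not called (median -2.27, adjusted p = 7.53e-13, adjusted p = 0.111 with an estimated correlation). In knockout the proximal tubule list had 1 higher, 28 lower and 1 not called, 1 higher and 29 lower adjusted over the list alone (median -1.66, adjusted p = 1.58e-10, adjusted p = 0.123 with an estimated correlation). The glucose transporter gene Slc2a2 fell by 2.32 ± 0.17 log2 units in wild type, the gluconeogenic gene G6pc changed by -3.34 ± 0.26 and -2.66 ± 0.22, Fbp1 by -2.69 ± 0.24 in wild type, and Hnf4a, a regulator of proximal tubule identity, by -1.55 ± 0.13 in wild type. Distal tubule and collecting duct genes fell as well (1 higher, 17 lower and 7 not called, 1 higher and 18 lower adjusted over the list alone, median -0.99, adjusted p = 2.22e-05, adjusted p = 0.351 with an estimated correlation), with the kallikrein gene Klk1 at -3.25 ± 0.24 and -2.95 ± 0.20 and Calb1, a calcium-binding protein, at -3.48 ± 0.33 and -2.66 ± 0.27. In knockout the distal tubule and collecting duct list had 2 higher, 12 lower and 11 not called (median -0.47, adjusted p = 0.00927, adjusted p = 0.509 with an estimated correlation). Its knockout median with the sex-pattern covariate was -0.90 (2 higher and 15 lower, adjusted p = 8.36e-06), against -1.10 in wild type. The loop of Henle list did not pass in wild type (1 higher, 7 lower and 5 not called, 2 higher and 8 lower adjusted over the list alone, median -0.75, adjusted p = 0.0587, adjusted p = 0.513 with an estimated correlation). It fell in knockout (1 higher, 7 lower and 5 not called, median -0.62, adjusted p = 0.0385, adjusted p = 0.509 with an estimated correlation), with Cldn10, a tight-junction gene, at -1.75 ± 0.19 and -1.59 ± 0.16. The list passed in both genotypes with the sex-pattern covariate (medians -0.83 and -0.97, adjusted p = 0.0118 and 0.00140, and 0.372 and 0.243 with an estimated correlation). Without knockout day 0 replicate 1 or day 5 replicate 2 the knockout call ended (adjusted p = 0.0599 and 0.0559). Ces1g, a carboxylesterase gene, changed by -4.26 ± 0.91 and -5.27 ± 0.76 and Inmt, a methyltransferase gene, by -3.86 ± 0.57 and -5.11 ± 0.47. Ces1g in wild type was -1.92 without day 0 replicate 1 and -6.61 without replicate 2, and lost its call with limma-voom. Podocyte and endothelial genes did not pass in either genotype (adjusted p = 0.766 and 0.362, 0.734 and 0.543). In wild type their medians (-0.05, -0.09) and means (0.06, 0.05) had opposite signs.

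Lists of mitochondrial energy production fell in both genotypes. All 33 nuclear genes of oxidative phosphorylation were lower in both genotypes (median -1.27, adjusted p = 7.35e-23, adjusted p = 0.111 with an estimated correlation), for example Uqcrfs1 (-1.53 ± 0.09 and -1.51 ± 0.08), Sdhb (-1.53 ± 0.09 and -1.43 ± 0.08) and Ndufs1 (-1.63 ± 0.10 and -1.43 ± 0.09), subunits of the respiratory chain. In knockout the oxidative phosphorylation list had median -1.21, adjusted p = 7.96e-22, adjusted p = 0.123 with an estimated correlation. All 13 tested genes of the mitochondrial genome were lower too (median -1.58, adjusted p = 5.2e-10, adjusted p = 0.111 with an estimated correlation). In knockout the mitochondrial genome list had median -1.50, adjusted p = 3.73e-09, adjusted p = 0.123 with an estimated correlation. Fatty acid oxidation and peroxisome genes had 0 higher, 26 lower and 4 not called (median -1.22, adjusted p = 1.3e-13, adjusted p = 0.111 with an estimated correlation), with Hadh at -1.76 ± 0.10 and -1.68 ± 0.08 and Etfa at -1.47 ± 0.10 and -1.59 ± 0.08. In knockout the fatty acid oxidation list had 1 higher, 26 lower and 3 not called (median -0.91, adjusted p = 7.08e-10, adjusted p = 0.123 with an estimated correlation). Antioxidant enzyme genes fell (2 higher, 18 lower and 6 not called, 4 higher and 18 lower adjusted over the list alone, median -0.85, adjusted p = 4.95e-06, adjusted p = 0.135 with an estimated correlation). In knockout the antioxidant enzymes list had 4 higher, 21 lower and 1 not called (median -0.88, adjusted p = 6.63e-07, adjusted p = 0.123 with an estimated correlation). Catalase (Cat) changed by -1.93 ± 0.10 and -1.85 ± 0.08 log2 units, the mitochondrial superoxide dismutase gene Sod2 by -1.65 ± 0.09 and -1.51 ± 0.08 and the methionine sulfoxide reductase gene Msra by -1.43 ± 0.08 and -1.28 ± 0.07. Targets of NRF2, the transcription factor of the oxidative stress response, fell as a list (3 higher, 16 lower and 8 not called, 4 higher and 17 lower adjusted over the list alone, median -0.53, adjusted p = 0.00437, adjusted p = 0.367 with an estimated correlation). In knockout the NRF2 target genes list had 6 higher, 14 lower and 7 not called (median -0.46, adjusted p = 0.0384, adjusted p = 0.509 with an estimated correlation). Abcc2, a transporter gene, changed by -1.33 ± 0.15 and -1.23 ± 0.13, while the carbonyl reductase gene Cbr3 rose by 1.79 ± 0.24 and 1.54 ± 0.20. The knockout call on NRF2 targets ended with the sex-pattern covariate (adjusted p = 0.0532) and without wild type day 0 replicate 1 or 2, or knockout day 0 or day 5 replicate 1 (adjusted p = 0.0607, 0.0597, 0.0559 and 0.0809). Both ended in the Y-linked libraries alone (adjusted p = 0.116 and 0.221). NADPH oxidase subunit genes, which produce superoxide, rose in wild type (7 higher, 1 lower and 3 not called, median 1.27, adjusted p = 0.0183, adjusted p = 0.293 with an estimated correlation). The list did not pass in knockout (5 higher, 2 lower and 4 not called, median 0.60, adjusted p = 0.0542, adjusted p = 0.396 with an estimated correlation), but it did with the sex-pattern covariate (median 0.95, adjusted p = 0.0445, and 0.242 with an estimated correlation). The wild type call ended in the Xist libraries alone (adjusted p = 0.0572). The phagocyte subunit gene Ncf1 rose by 2.75 ± 0.25 and 2.65 ± 0.21.

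**Figure D3:**
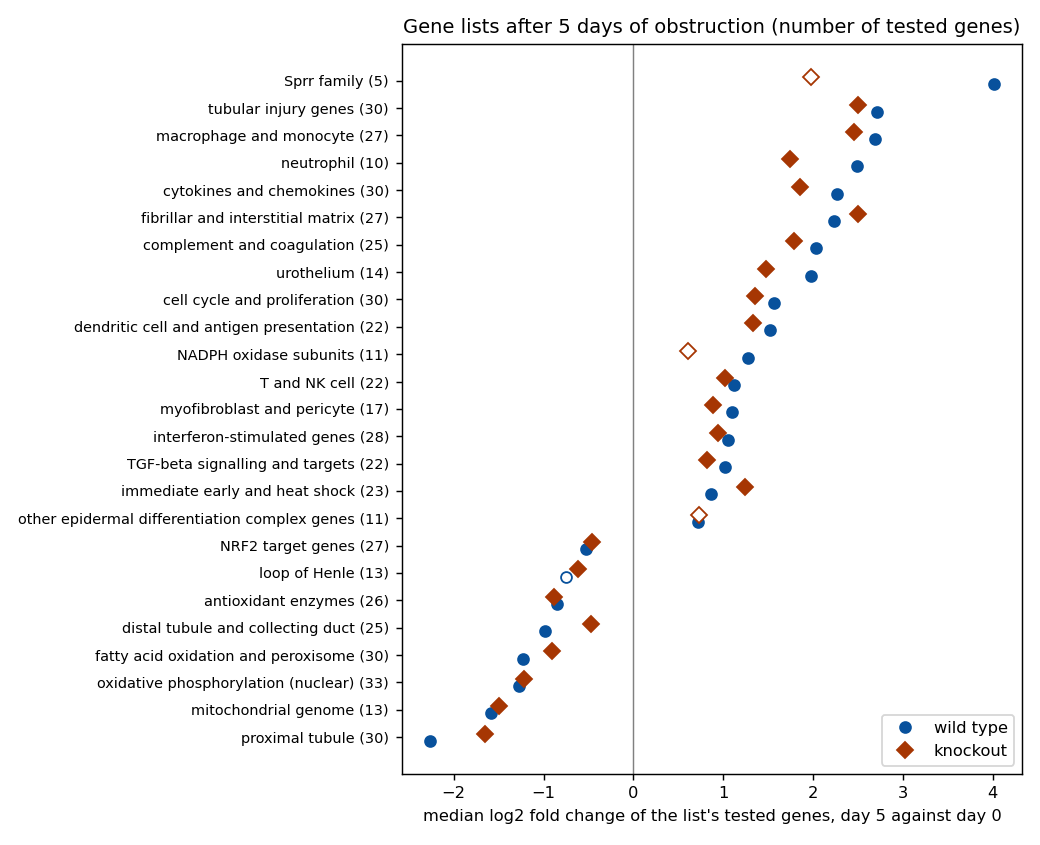
Median log2 fold change (day 5 against day 0) of the tested genes of each list that passed in at least 1 genotype, with circles for wild type and diamonds for knockout, filled where the list passed and open where it did not. Medians run from -2.27 and -1.66 for proximal tubule genes to 2.72 and 2.50 for tubular injury genes, and to 4.02 for the 5 Sprr genes in wild type.

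Scar-forming tissue genes rose. All 27 genes of the fibrillar and interstitial matrix were higher in both genotypes (median 2.23, adjusted p = 8.16e-14, adjusted p = 0.128 with an estimated correlation), with fibronectin (Fn1) at 2.87 ± 0.19 and 3.14 ± 0.16 and the collagen-degrading Mmp14 at 2.81 ± 0.14 and 2.81 ± 0.12. In knockout the fibrillar and interstitial matrix list had median 2.50, adjusted p = 2.38e-13, adjusted p = 0.143 with an estimated correlation. Myofibroblast and pericyte genes had 13 higher, 0 lower and 4 not called (median 1.09, adjusted p = 0.000158, adjusted p = 0.119 with an estimated correlation), smooth muscle actin (Acta2) rising by 1.81 ± 0.22 and 2.08 ± 0.19. In knockout the myofibroblast and pericyte list had 13 higher, 0 lower and 4 not called, 14 higher and 0 lower adjusted over the list alone (median 0.89, adjusted p = 0.000132, adjusted p = 0.123 with an estimated correlation). Genes of TGF-beta signalling, the main pro-fibrotic pathway, had 17 higher, 1 lower and 4 not called, 18 higher and 1 lower adjusted over the list alone (median 1.02, adjusted p = 2.54e-06, adjusted p = 0.0232 with an estimated correlation), Ltbp2, a latent TGF-beta binding protein gene, rising by 4.36 ± 0.33 and 3.88 ± 0.28. In knockout the TGF-beta signalling and targets list had 18 higher, 1 lower and 3 not called, 20 higher and 1 lower adjusted over the list alone (median 0.82, adjusted p = 1.93e-05, adjusted p = 0.0637 with an estimated correlation). The wild type TGF-beta list was the one list that passed in any comparison with an estimated correlation. With the sex-pattern covariate as well, it and the distal tubule list passed in wild type (adjusted p = 0.0308 and 0.0308 with an estimated correlation).

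Genes of infiltrating and inflammatory cells rose. Macrophage and monocyte genes had 24 higher, 0 lower and 3 not called (median 2.69, adjusted p = 2.25e-12, adjusted p = 0.119 with an estimated correlation), with the lysosomal protease gene Ctss at 3.08 ± 0.16 and 2.80 ± 0.14. In knockout the macrophage and monocyte list had 24 higher, 0 lower and 3 not called (median 2.45, adjusted p = 1.33e-11, adjusted p = 0.123 with an estimated correlation). Neutrophil genes had 9 higher, 0 lower and 1 not called (median 2.48, adjusted p = 0.00101, adjusted p = 0.327 with an estimated correlation), with the alarmin gene S100a8 at 3.76 ± 0.56 and 2.27 ± 0.47. In knockout the neutrophil list had 8 higher, 0 lower and 2 not called, 9 higher and 0 lower adjusted over the list alone (median 1.74, adjusted p = 0.0188, adjusted p = 0.480 with an estimated correlation). T and NK cell genes had 18 higher, 0 lower and 4 not called, 19 higher and 0 lower adjusted over the list alone (median 1.12, adjusted p = 0.000121, adjusted p = 0.246 with an estimated correlation). In knockout the T and NK cell list had 18 higher, 0 lower and 4 not called (median 1.02, adjusted p = 9.93e-05, adjusted p = 0.232 with an estimated correlation). Dendritic cell and antigen presentation genes had 21 higher, 0 lower and 1 not called in both genotypes (median 1.52, adjusted p = 3.16e-11, adjusted p = 0.119 with an estimated correlation), the class II gene H2-Eb1 rising by 2.46 ± 0.15 and 1.94 ± 0.13. In knockout the dendritic cell and antigen presentation list had median 1.33, adjusted p = 3.26e-09, adjusted p = 0.154 with an estimated correlation. Cytokines and chemokines had 25 higher, 1 lower and 4 not called (median 2.27, adjusted p = 2.19e-07, adjusted p = 0.119 with an estimated correlation). In knockout the cytokines and chemokines list had 21 higher, 1 lower and 8 not called (median 1.86, adjusted p = 1.26e-05, adjusted p = 0.189 with an estimated correlation). Among them the neutrophil chemokine gene Cxcl2 rose by 5.34 ± 0.36 and 4.59 ± 0.30 and the cytokine gene Lif by 4.97 ± 0.26 and 4.30 ± 0.22. Interferon-stimulated genes had 22 higher, 0 lower and 6 not called, 23 higher and 0 lower adjusted over the list alone (median 1.06, adjusted p = 7.24e-07, adjusted p = 0.293 with an estimated correlation). In knockout the interferon-stimulated genes list had 21 higher, 2 lower and 5 not called, 21 higher and 3 lower adjusted over the list alone (median 0.94, adjusted p = 4.11e-05, adjusted p = 0.396 with an estimated correlation). Complement and coagulation genes had 17 higher, 2 lower and 6 not called (median 2.03, adjusted p = 5.65e-06, adjusted p = 0.111 with an estimated correlation), C3 rising by 5.48 ± 0.52 and 5.55 ± 0.44. In knockout the complement and coagulation list had 19 higher, 2 lower and 4 not called (median 1.78, adjusted p = 3.05e-05, adjusted p = 0.123 with an estimated correlation). B and plasma cell genes did not pass (adjusted p = 0.121 and 0.292).

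Cell cycle genes rose in both genotypes (28 higher, 1 lower and 1 not called, median 1.57, adjusted p = 6.43e-08, adjusted p = 0.327 with an estimated correlation), the mitotic kinase gene Aurkb by 1.98 ± 0.31 and 1.61 ± 0.26. In knockout the cell cycle and proliferation list had 27 higher, 0 lower and 3 not called, 28 higher and 0 lower adjusted over the list alone (median 1.36, adjusted p = 1.89e-06, adjusted p = 0.406 with an estimated correlation). Immediate early and heat shock genes rose too (13 higher, 4 lower and 6 not called, 14 higher and 4 lower adjusted over the list alone, median 0.86, adjusted p = 0.0303, adjusted p = 0.465 with an estimated correlation), Junb by 2.63 ± 0.22 and 2.40 ± 0.19. In knockout the immediate early and heat shock list had 16 higher, 1 lower and 6 not called, 17 higher and 1 lower adjusted over the list alone (median 1.24, adjusted p = 0.000439, adjusted p = 0.296 with an estimated correlation). The wild type call on this list ended without day 0 replicate 1 or day 5 replicate 2 (adjusted p = 0.0868 and 0.0745). Lists that passed in neither genotype had these adjusted p values: p53 targets and apoptosis 0.296 and 0.171, glycolysis and hypoxia 0.121 and 0.274, unfolded protein response 0.982 and 0.322, and circadian clock 0.296 and 0.543. With the sex-pattern covariate p53 targets were higher in knockout obstruction (median 0.29, adjusted p = 0.0486, and 0.204 with an estimated correlation). Markers of adjoining tissues did not pass either: adipocyte genes had medians of 0.88 and -0.68 (adjusted p = 0.347 and 0.150), skeletal muscle genes -0.57 and 0.66 (0.323 and 0.856), and erythroid genes 2.04 and 0.13 (0.494 and 0.466). Median and mean differed in sign for circadian (mean -0.30) and unfolded protein response genes (median -0.06, mean 0.14) in wild type, and for glycolysis and hypoxia (median -0.0044, mean 0.01), skeletal muscle (mean -0.36) and erythroid genes (mean -0.16) in knockout. Too few genes of the adrenal (3) and pancreas (1, Cela1) lists were expressed for a test, with highest scaled CPM of 6 and 169. None of the 14 symbols of the replication-dependent histone list matched the file, which gives newer symbols. Matched by gene identifier, after the data had been seen, all 14 were in the file and 9 were tested. As one of 38 lists they were lower after obstruction in wild type (0 higher, 5 lower and 4 not called, median -1.07, adjusted p = 0.00278, and 0.123 with an estimated correlation) and in knockout (0 higher, 5 lower and 4 not called, -0.51, 0.0359, and 0.285 with an estimated correlation). The knockout value ran up to 0.0554 without 1 library, and the list passed in none of the 4 genotype comparisons (adjusted p = 0.0729 to 0.787). For genotype at day 5 and for the interaction it did pass in at least 1 of the fits without 1 library. Adding it brought the Sprr list in knockout to an adjusted p of 0.0499 and changed no other call.

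Before obstruction, knockout kidneys (n = 4) differed from wild type kidneys (n = 2) in 3 genes, all lower in knockout. Noct, which encodes the clock-controlled enzyme nocturnin, stood at 70.2 ± 15.8 scaled CPM (SD) in wild type and 14.9 ± 1.61 in knockout, a log2 fold change of -2.19 ± 0.20 (SE, adjusted p = 0.00150). Zbtb16, a transcriptional repressor gene induced by glucocorticoids, stood at 26.7 ± 1.21 and 3.39 ± 1.13 (-2.85 ± 0.35, adjusted p = 0.0236), and Jarid2, a subunit gene of a chromatin-silencing complex, at 111 ± 26.8 and 52.8 ± 2.89 (-1.05 ± 0.13, adjusted p = 0.0236). At day 5 the same genes differed by 0.07, 0.07 and 0.12 log2 units.

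**Figure D4:**
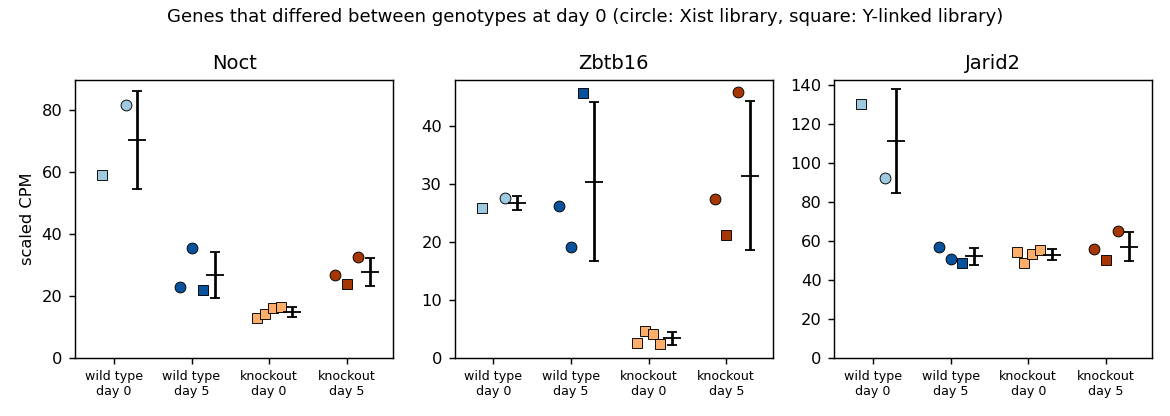
Scaled CPM of Noct, Zbtb16 and Jarid2 in each library of the 4 groups, with circles for Xist libraries, squares for Y-linked libraries, and black marks for the group mean ± SD. The 4 knockout libraries at day 0 lie at 12.9 to 16.3 (Noct), 2.38 to 4.56 (Zbtb16) and 48.7 to 55.2 (Jarid2), below both wild type libraries at day 0.

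No gene was higher at day 0 by limma, where 1502 genes were higher and 1207 lower at an unadjusted p under 0.05 (905 of both kinds would be by chance). edgeR on the recovered reads also gave 0 higher and 3 lower, limma-voom 0 and 2, and DESeq2 225 and 145. With 2 wild type libraries, 1 of each sex pattern, against 4 Y-linked knockout libraries, the count depended on which wild type library was used. It was 421 higher and 217 lower without replicate 1, the Y-linked one. It was 13 and 22 without knockout day 5 replicate 2, or 4 and 16 without replicate 3. With the sex pattern as a covariate there were 4 higher and 15 lower, and the 3 genes had log2 fold changes of -2.00, -2.89 and -1.04. Noct kept its call in each of the 12 fits without 1 library. Zbtb16 lost its call without wild type day 0 replicate 2, knockout day 0 replicate 1 or knockout day 5 replicate 1, and Jarid2 without wild type day 5 replicate 2, knockout day 0 replicate 1, 2 or 3, or knockout day 5 replicate 1. Both also lost it with the 1.5-fold threshold, and Zbtb16 with limma-voom and in Y-linked libraries alone. Over all alternatives the adjusted p ran from 6.23e-21 to 0.0267 for Noct, 1e-11 to 0.229 for Zbtb16 and 6.99e-09 to 1 for Jarid2.

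Of 37 gene lists, 7 differed at day 0 and none did with an estimated correlation (smallest adjusted p = 0.802 with an estimated correlation), and no member passed over all genes. Circadian clock genes were lower (median -0.50, adjusted p = 0.00544, 2 higher and 7 lower adjusted over the list alone). Among them Per1 stood at -1.49 ± 0.35, Usp2 at -0.98 ± 0.20 and, in the other direction, Npas2 at 1.35 ± 0.28 (adjusted p = 0.115, 0.0810 and 0.0873). Immediate early and heat shock genes were lower (median -0.30, adjusted p = 0.00450), Hspa1b at -0.80 ± 0.24. Higher in knockout were antioxidant enzyme genes (median 0.17, adjusted p = 0.00377, with Sod1 at 0.43 ± 0.12), nuclear genes of oxidative phosphorylation (0.13, 0.000177, with Ndufa4 at 0.34 ± 0.11) and antigen presentation genes (0.26, 0.00995, H2-Eb1 at 0.50 ± 0.14, 2 higher adjusted over the list alone). Podocyte and distal tubule genes were lower (medians -0.27 and -0.25, adjusted p = 0.0146 and 0.0122), calls that ended with the sex-pattern covariate (adjusted p = 0.241 and 0.920). That covariate takes the sex difference to be equal in all groups. The knockout day 0 libraries, all Y-linked, add nothing to its estimate. With the covariate 12 lists differed at day 0. The 7 it added were cell cycle (median -0.33, adjusted p = 0.000947), tubular injury (-0.28, 0.00242), matrix (-0.21, 0.00468), NRF2 target (-0.14, 0.0329) and unfolded protein response genes (-0.15, 0.0463), lower in knockout, and proximal tubule (0.19, 0.0399) and loop of Henle genes (0.16, 0.0433), higher. None passed with an estimated correlation (adjusted p = 0.705 each). The immediate early median became -0.19. Without wild type replicate 2 the circadian, immediate early, podocyte and distal tubule calls ended (adjusted p = 0.0751, 0.147, 0.597 and 0.651). The antigen presentation call ended without wild type replicate 1 or knockout replicate 1 (0.247 and 0.0866), and the distal tubule call also without knockout replicate 4 (0.0768).

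In obstructed kidneys the question is how loss of Sprr2f changes the injured organ (n = 3 per genotype). Proximal tubule, oxidative phosphorylation and fatty acid oxidation lists were higher and neutrophil, cell cycle and interferon lists lower in knockout at the fixed correlation (medians 0.51, 0.18, 0.20, -0.97, -0.35 and -0.25 log2 units). None of the 6 passed with an estimated correlation (adjusted p = 0.137, 0.281, 0.281, 0.137, 0.335 and 0.335). Erythroid and adipocyte markers were also lower (adjusted p = 0.335 each with an estimated correlation). All 30 proximal tubule genes were higher (adjusted p = 1.39e-12, and 0.137 with an estimated correlation, 3 higher adjusted over the list alone). Slc2a2 stood at 0.68 ± 0.15 (SE) and Hnf4a at 0.39 ± 0.11. All 10 neutrophil genes were lower (adjusted p = 5.94e-12, and 0.137 with an estimated correlation, 5 lower adjusted over the list alone), S100a8 at -1.87 ± 0.51 and Cxcr2 at -1.16 ± 0.28. None of these genes passed over all genes. Knockout replicate 2 (mean log2 value 2.16) overlapped wild type (2.07 to 2.70), unlike the other knockouts (1.13 and 0.689). For proximal tubule genes it lay just above wild type (7.51 against 7.49).

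At day 5 limma called 0 genes higher and 0 lower, with 648 higher and 377 lower at an unadjusted p under 0.05 against 905 by chance, and a smallest adjusted p of 0.152. edgeR and limma-voom also called 0 and 0, and DESeq2 49 higher and 2 lower. Without knockout day 5 replicate 2, the Y-linked one, 15 genes were higher and 8 lower (S100a8 among them), 1 and 1 without replicate 3, and 0 and 1 without replicate 1. The sex-pattern covariate gave 2 higher and 1 lower: Slc25a15, the mitochondrial ornithine carrier gene (0.50 ± 0.07, from 55.3 ± 2.71 to 78.5 ± 7.02 scaled CPM), Ces1d, a carboxylesterase gene, and Sprr2f. Slc25a15 and Ces1d were chosen after their values were seen.

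Of the 37 lists, 19 differed at day 5 and none did with an estimated correlation (smallest adjusted p = 0.137, for the proximal tubule, neutrophil and TGF-beta lists). Besides the proximal tubule list, 5 were higher in knockout: oxidative phosphorylation (33 of 33 genes above wild type, median 0.18, adjusted p = 5.74e-17, 1 higher adjusted over the list alone), fatty acid oxidation (29 of 30, 0.20, 6.77e-08), antioxidant enzymes (0.14, 0.000355, 1 higher adjusted over the list alone), distal tubule (0.17, 0.00105) and mitochondrial genome (0.07, 0.0173). Atp5o, an ATP synthase subunit gene, stood at 0.57 ± 0.14, Etfb, an electron transfer gene of fatty acid oxidation, at 0.50 ± 0.16, and Msra at 0.32 ± 0.08. Lower in knockout were cell cycle genes (29 of 30 below wild type, -0.35, 5.85e-10), interferon-stimulated genes (26 of 28, -0.25, 1.8e-09, with Isg15 at -0.73 ± 0.20), tubular injury genes (27 of 30, -0.25, 3.1e-05, Clu at -0.33 ± 0.12) and urothelial genes (14 of 14, -0.51, 0.000107). So were cytokines and chemokines (-0.19, 3.29e-05, Il1b at -0.89 ± 0.34), TGF-beta signalling (-0.14, 0.000896), myofibroblast (-0.16, 0.0140, 1 lower adjusted over the list alone), antigen presentation (-0.08, 0.0173), complement (-0.05, 0.0330) and Sprr genes (-0.49, 0.0452, 1 higher and 1 lower adjusted over the list alone). The Sprr call rests on Sprr2f itself, the gene knocked out: the other 4 genes had a median of -0.24, a mean of -0.06 and an adjusted p of 0.469 (0.757 with an estimated correlation). Transcripts of other tissues moved in the same comparison: erythroid genes (median -2.08, adjusted p = 2.25e-05, 6 lower adjusted over the list alone) and adipocyte genes (-1.64, 6.09e-07) were lower in knockout. The adjusted p of these 19 lists with an estimated correlation ran from 0.137 to 0.589. Matrix and macrophage genes did not pass (medians -0.06 and -0.05, adjusted p = 0.103 and 0.469).

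Of the 19 lists, 11 passed in the same direction in each of the 6 fits without 1 day 5 library. The antioxidant call ended without knockout replicate 2 (adjusted p = 0.123), and the distal tubule call without wild type replicate 3 or knockout replicate 1 (0.634 and 0.174). Myofibroblast genes lost theirs without wild type replicate 3 or knockout replicate 2 (0.133 and 0.279), urothelial genes without wild type or knockout replicate 3 (0.496 and 0.0555), and antigen presentation genes without wild type or knockout replicate 1 (0.263 and 0.241). Sprr, complement and mitochondrial genome genes each lost theirs without several libraries (up to 0.239 without knockout replicate 1, 0.407 without knockout replicate 3 and 0.501 without wild type replicate 1). With the sex-pattern covariate the complement call ended (adjusted p = 0.0515), and the sex-dimorphic (median 0.25, 0.00210) and other epidermal lists (-0.04, 0.0486) passed, neither with an estimated correlation (adjusted p = 0.227 and 0.331). With that covariate cell cycle, tubular injury and proximal tubule genes already differed at day 0 in the direction they had at day 5. Between the Y-linked day 5 libraries, 1 of each genotype, the tubular injury, cytokine and erythroid medians had the other sign (0.11, 0.18 and 0.23) from those between the Xist libraries (-0.45, -0.56 and -3.29). Medians with 1 sign but of different size in Y-linked and Xist libraries were those of proximal tubule (0.20 and 0.60), adipocyte (-0.23 and -1.89), urothelial (-0.90 and -0.32), myofibroblast (-0.45 and -0.04), complement (-0.05 and -0.25), antioxidant (0.22 and 0.07) and mitochondrial genome genes (0.09 and 0.21). Library means of 5 of all 37 tested lists did not overlap between genotypes (proximal tubule, oxidative phosphorylation, fatty acid oxidation, cell cycle and antigen presentation), where chance separates 10% of lists with 3 against 3.

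**Figure D5:**
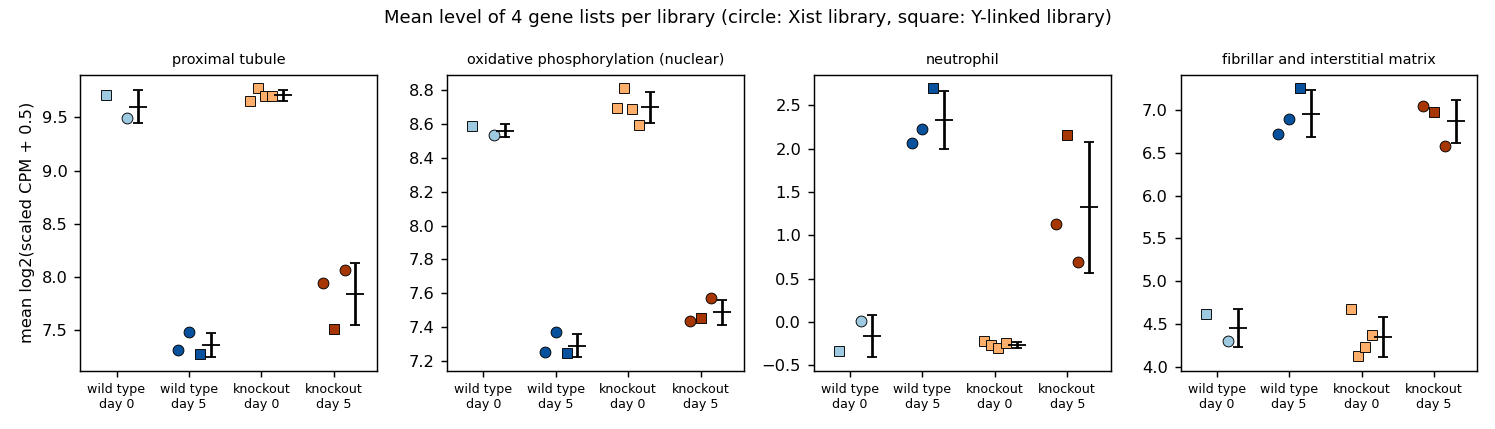
Mean log2(scaled CPM + 0.5) of the genes of 4 lists in each library, with circles for Xist libraries, squares for Y-linked libraries, and black marks for the group mean ± SD. Proximal tubule genes lay lower in all 3 wild type than in all 3 knockout libraries at day 5 (adjusted p = 1.39e-12, and 0.137 with an estimated correlation), while matrix genes overlapped (adjusted p = 0.103).

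Whether the response to obstruction differed between genotypes was tested as an interaction. Noct was the one gene to pass by limma (2.26 ± 0.27 log2 units, SE, adjusted p = 0.0356, 713 genes higher and 663 lower at an unadjusted p under 0.05). It fell during obstruction in wild type (from 70.2 ± 15.8 to 26.7 ± 7.48 scaled CPM) and rose in knockout (from 14.9 ± 1.61 to 27.7 ± 4.53). Sprr2f had a difference of -4.26 ± 0.86 (adjusted p = 0.333). Noct kept its call in 3 of the 12 fits without 1 library. These were the fits without wild type day 0 replicate 1, wild type day 5 replicate 2 or knockout day 5 replicate 2. Its adjusted p over all alternatives ran from 1.32e-10 to 0.376. For the interaction edgeR and limma-voom gave 1 higher and 0 lower, and DESeq2 35 and 12. The counts were 43 and 64 without wild type day 0 replicate 1 and 12 and 3 without knockout day 5 replicate 2.

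The interaction test called 9 lists, and none with an estimated correlation (smallest adjusted p = 0.616 with an estimated correlation). Proximal tubule genes fell less in knockout (median difference 0.46, adjusted p = 3.17e-05, 23 of 30 genes, 1 higher adjusted over the list alone), as did distal tubule genes (0.42, 3.17e-05, 24 of 25 genes) and fatty acid oxidation genes (0.26, 3.17e-05, 23 of 30 genes, 3 higher adjusted over the list alone). Antigen presentation genes rose less (-0.39, 3.17e-05, 20 of 22 genes), and so did cytokines and chemokines (-0.54, 0.00295, 23 of 30 genes), while immediate early and heat shock genes rose more (0.21, 0.00295, 17 of 23 genes, 3 higher adjusted over the list alone). Adipocyte (-2.60, 5.18e-05, 1 higher and 2 lower adjusted over the list alone), erythroid (-1.72, 0.0426) and skeletal muscle genes (0.43, 0.0426) differed as well. All 9 calls stayed with the sex-pattern covariate, with smaller medians for proximal tubule (0.24) and distal tubule genes (0.18) and a larger one for skeletal muscle genes (0.73). It added 6 lists: NRF2 targets (median 0.19, adjusted p = 0.00148), unfolded protein response (0.15, 0.0250) and mitochondrial genome (0.12, 0.0359), and, in the other direction, interferon-stimulated (-0.21, 0.00469), TGF-beta (-0.21, 0.0294) and T and NK cell genes (-0.36, 0.0388). None of the 15 passed with an estimated correlation. No other list passed, so the calls of Sprr, loop of Henle, NADPH oxidase and other epidermal genes in 1 genotype alone were not shown to differ between genotypes (adjusted p = 0.461, 0.939, 0.343 and 0.0834, and 0.777, 0.175, 0.777 and 0.437 with the covariate). Without wild type day 0 replicate 1 the cytokine, fatty acid oxidation, adipocyte, skeletal muscle and erythroid calls ended (adjusted p = 0.420, 0.0938, 0.265, 0.126 and 0.0938). The immediate early call ended without wild type day 0 replicate 2 or knockout day 5 replicate 2 (0.110 and 0.0843), and the skeletal muscle call also without wild type day 5 replicate 1 or knockout day 5 replicate 2 or 3 (0.0865, 0.0656 and 0.0514). Erythroid genes passed without wild type day 5 replicate 3, knockout day 0 replicate 4 or knockout day 5 replicate 1 (3.15e-08, 0.0451 and 0.0413) and in none of the other 9 fits without 1 library (up to 0.247 without wild type day 5 replicate 1).

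Averaged over both days, the comparison that asks what loss of Sprr2f changed regardless of obstruction, knockout kidneys (n = 7) held more of the succinate receptor transcript Sucnr1 and less Noct than wild type kidneys (n = 5). Sucnr1 stood at 12.9 ± 0.484 and 33.4 ± 7.61 scaled CPM (SD) in wild type and knockout at day 0 and at 2.90 ± 0.419 and 4.94 ± 0.503 at day 5, a log2 difference of 0.996 ± 0.129 (SE, adjusted p = 0.0377). Noct differed by -1.06 ± 0.14 (adjusted p = 0.0377), with a difference of 0.07 at day 5, and Sprr2f by -2.02 ± 0.43 (adjusted p = 0.116). By limma 1451 genes were higher and 873 lower at an unadjusted p under 0.05. edgeR also called 1 higher and 1 lower, limma-voom 0 and 0, and DESeq2 323 and 81. Sucnr1 kept its call in 4 of the 12 fits without 1 library (those without wild type day 0 replicate 1, knockout day 0 replicate 3 or 4, or knockout day 5 replicate 2). Noct kept its call in 2 (without wild type day 0 replicate 1 or knockout day 5 replicate 2). Without these last 2 libraries 317 genes were higher and 99 lower, and 14 higher and 5 lower. Both lost their calls with limma-voom, with no filter, with the 1.5-fold threshold and in Y-linked libraries alone. The adjusted p over all alternatives ran from 1e-08 to 1 for Sucnr1 and from 2.4e-09 to 1 for Noct.

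Among the lists, 12 differed in the averaged comparison and none with an estimated correlation (smallest adjusted p = 0.648 with an estimated correlation). No list member passed over all genes. All 33 nuclear genes of oxidative phosphorylation lay above wild type in knockout (median 0.16, adjusted p = 3.08e-14, 15 higher adjusted over the list alone). Higher as lists were also antioxidant enzyme genes (0.17, 5.82e-05, 6 higher adjusted over the list alone) and proximal tubule genes (0.16, 0.000618, 3 higher adjusted over the list alone). Lower in knockout were interferon-stimulated (-0.18, 7.5e-05), cell cycle (-0.20, 0.00106), tubular injury (-0.13, 0.00432, 2 lower adjusted over the list alone) and neutrophil genes (-0.60, 0.00619, 6 lower adjusted over the list alone). So were circadian (-0.26, 0.00226, 2 higher and 7 lower adjusted over the list alone), podocyte (-0.10, 0.00551, 1 lower) and myofibroblast genes (-0.17, 0.0177, 3 lower), and also erythroid (-1.17, 0.0177) and immediate early genes (-0.21, 0.0245). The podocyte, immediate early and erythroid calls ended with the sex-pattern covariate (adjusted p = 0.0782, 0.0585 and 0.0585). Larger medians were those of proximal tubule (0.35), cell cycle (-0.37) and tubular injury genes (-0.24). Passing with it were also urothelial (-0.49, 0.000178), matrix (-0.14, 0.00120) and adipocyte genes (-0.46, 0.0491), lower in knockout, and distal tubule genes (0.08, 0.0386), higher, but none of its 13 calls with an estimated correlation. Calls that ended without wild type day 0 replicate 1 were those of cell cycle, myofibroblast and erythroid genes (adjusted p = 0.934, 0.277 and 0.194). Those of podocyte, neutrophil, tubular injury and immediate early genes ended without replicate 2 (0.167, 0.0880, 0.0561 and 0.451). Without wild type day 5 replicate 1 the erythroid call ended (0.0666), and without knockout day 5 replicate 2 the podocyte and myofibroblast calls (0.203 and 0.0837). The immediate early call also ended without wild type day 5 replicate 2, knockout day 0 replicate 1 or 2, or knockout day 5 replicate 1 (0.260, 0.0524, 0.0584 and 0.104).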

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

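All tests of an explanation in this part were chosen after the result was seen, except the counts over other splits of the samples.

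The series title gives female mice, while 7 of 12 libraries held Y-linked transcripts and 5 held Xist. RNA of both sexes mixed within libraries was excluded: no library held more than 0.706% of the other pattern's mean level. The presence of mice of both sexes is a candidate explanation, since 15 of 15 tested genes of the sex-dimorphic renal list differed with the pattern within groups. Mislabelled samples cannot be told apart from this. In a check of labels, 0 of 12 libraries lay nearer the other day in mitochondrial share, and 0 of 6 at day 5 nearer the other genotype in Sprr2f. Sprr2f does not separate the genotypes at day 0, so the genotype of those 6 libraries was not checked. This check cannot decide the matter. Labels exchanged among kidneys of 1 sex could not bring in Y-linked transcripts, and an exchange with samples from outside the series would not show. The labels name no sex per sample, so beyond that count no biological explanation was tested.

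Noct, Zbtb16 and Jarid2 were lower in knockout kidneys at day 0. An unequal sex make-up as the whole cause was argued against, because Noct kept a log2 fold change of -2.00 ± 0.17 (SE) with the sex pattern as a covariate. This holds only if the sex difference is equal in all groups. An effect of the knockout at both days was excluded only down to a set size. At day 5 Noct, Zbtb16 and Jarid2 differed by 0.0715 ± 0.187, 0.0674 ± 0.334 and 0.125 ± 0.127 log2 units. The lower bounds of 2 SE (-0.303, -0.600 and -0.130) excluded falls of the set sizes (-1.10, -1.42 and -0.525), and smaller effects stay open. Time of day or feeding state may explain the pattern and cannot be told apart from genotype. Circadian genes moved with Noct (list adjusted p = 0.00544, and 0.802 with an estimated correlation), but the labels give no collection times. With 2 wild type kidneys, litter or cage differences stay open too, untested.

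At day 5, 19 lists differed between genotypes at the fixed correlation and 0 of 37 with an estimated one (smallest adjusted p = 0.137). The kidneys taken singly may account for part of this, since 11 of 19 lists kept call and direction in each of the 6 fits without 1 day 5 library and 8 did not. A uniformly smaller response to obstruction in knockout stays open: the day 5 difference, as a share of the mean response, was 19.8 percentage points larger for proximal tubule than for matrix genes (95% interval -5.41 to 45.0), a test whose threshold was changed after its value was seen. The first threshold, 2 SE (SE 9.07), would have counted this value against that explanation. Both thresholds treat the mean response as fixed and leave out its error. The 10 splits of 3 against 3 are too few for a share under 0.05; the real split gave 19 lists and 0 genes (by limma; 648 higher and 377 lower at an unadjusted p under 0.05, 49 and 2 by DESeq2), and the highest others 18 lists and 22 genes. The other splits, which mixed the genotypes, gave 12, 17, 18, 10, 18, 5, 4, 18 and 14 lists, so several came close to the real split. The 4 splits with both Y-linked libraries on 1 side called 22, 18, 1 and 0 genes.

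Among the 4 knockout libraries at day 0, 1 library lay apart from the rest, by the gap to its neighbour over the whole range, for 3 of 109 genes and 1 of 37 lists, where chance marks about 1 in 20 groups (5.45 genes). These were Krt20 (0.854; 1.61 scaled CPM in replicate 4 against 0.304 to 0.495), Npas2 (0.870; 17.9 in replicate 2 against 12.9 to 13.5), Trpv5 (0.968; 16 in replicate 1 against 20.1 to 20.2) and the fatty acid oxidation list (0.955; mean log2 value 7.43 in replicate 2 against 7.17 to 7.18).

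The interaction test called Noct (2.26 log2 units) and, with the fixed correlation alone, 9 lists. The lists were proximal tubule, distal tubule, antigen presentation and fatty acid oxidation (adjusted p = 3.17e-05 each), adipocyte (5.18e-05), cytokines and immediate early genes (0.00295 each), and skeletal muscle and erythroid genes (0.0426 each). For Noct this was largely the day 0 difference (-2.19 ± 0.20, SE), since the genotypes differed by 0.07 log2 units at day 5. Its call did not hold in every fit without 1 library.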

How the results depend on the processing

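The alternatives chosen after the data had been seen, the histone list among them, are named above. Of 6848 values for single genes over all alternatives, 6719 kept direction and call, 74 lost and 53 gained a call and 2 reversed. Of 1899 for single lists, 1604 were kept, 288 lost and 7 reversed. Counts stayed within 1.5 times in 231 of 336 for genes and 101 of 122 for lists. Agreement between genotypes counted as kept in 28 of 28, even at 0.821 against r = 0.904, so that count says little about stability. A single gene called in neither fit counted as kept, so the share kept says little about the calls between genotypes. Counts are given as higher and lower, and those not given stayed within 1.5 times. Library size only gave 8569 and 2000 for wild type obstruction, 10117 and 2175 for knockout obstruction, 2 and 13 for genotype at day 0, 0 higher for the interaction and 2 lower for the average. The 1.5-fold threshold gave 1712 and 1285, 1697 and 1419, 1 lower at day 0, 0 higher for the interaction, and 0 and 0 for the average. DESeq2 gave 225 and 145 at day 0, 49 and 2 at day 5, 35 and 12 for the interaction, and 323 and 81 for the average. At day 0, robust edgeR gave 3 and 10, RLE 3 higher, upper-quartile 2 higher, no filter 2 and 7, the stricter filter 2 higher, the compared groups alone 2 and 8, pseudocount 0.1 3 and 5, pseudocount 1 1 higher, the sex covariate 4 and 15, and Y-linked libraries alone 1 higher. At day 5, pseudocount 1 gave 2 lower and the sex covariate 2 and 1. The interaction had 0 higher with no filter or in Y-linked libraries alone and 3 with the sex covariate. For the average, voom, no filter and Y-linked libraries alone gave 0 and 0, robust edgeR 2 higher and the sex covariate 8 and 4. Sprr2f in knockout obstruction lost its call with voom (2.52), no filter (1.49), the 1.5-fold threshold (1.49) and pseudocount 0.1 (2.33); at day 5 it gained one with pseudocount 1 (-3.69) and the sex covariate (-4.14). With an estimated correlation 1 list passed in wild type obstruction and 0 in the other 5 comparisons. Directional fry passed 30 lists in each obstruction comparison and 0 in the other 4. Mixed fry passed 35, 3, 0, 0 and 3 for knockout obstruction, day 0, day 5, interaction and average. The sex covariate gave 12 lists at day 0 and 15 for the interaction, and Y-linked libraries alone 15 and 17. The fit on Y-linked libraries alone compares 1 wild type with 1 knockout library at day 5, its spread coming from the 4 knockout day 0 libraries, so its p-values carry little weight. In it, Il6 (0.20) and Hbb-bs (0.23) at day 5 reversed, and camera gave the other direction, relative to all genes, for the lists tubular injury (adjusted p = 0.348), cytokines (0.00209), complement (0.963), mitochondrial genome (0.149) and erythroid (0.348) at day 5, erythroid for the interaction (0.0284) and immediate early for the average (0.114). The medians of complement (-0.05) and mitochondrial genome genes (0.09) at day 5 kept their sign. Leaving out 1 library at a time gave ranges of 3534 to 4679 and 3440 to 4271 for wild type obstruction, 4593 to 5267 and 4219 to 4808 for knockout, 0 to 421 and 1 to 217 at day 0, 0 to 15 and 0 to 8 at day 5, 0 to 43 and 0 to 64 for the interaction, and 0 to 317 and 0 to 99 for the average. Sprr2f ranged from 5.36 to 5.92 in wild type obstruction, 0.86 to 2.36 in knockout, -4.76 to -3.26 at day 5, -4.87 to -3.37 for the interaction and -2.32 to -1.58 for the average, and lists from 23 to 25, 21 to 24, 7 to 9, 17 to 20, 7 to 15 and 10 to 14. The correlation between genotypes ran from 0.821 to 0.917. Where 1 wild type library was left at day 0, it was assumed to vary like the other groups. The cause was not tested. Some comparisons had no fit in the Y-linked or Xist libraries alone and were not run. No paired analysis was possible because each sample has its own number in the labels.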

Other observations

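The second principal component of the libraries, with 9.48% of the variance after 73.9% for the first, separated the 7 Y-linked from the 5 Xist libraries, and genes of renal transport and detoxification were among those that differed. Slc7a13, an amino acid transporter gene of the proximal tubule, was higher in Y-linked libraries by 5.71 ± 0.27 log2 units (SE), the cytochrome genes Cyp2j13 by 4.65 ± 0.48, Cyp7b1 by 3.27 ± 0.29 and Cyp4b1 by 3.09 ± 0.27. Higher in Xist libraries were the glucuronosyltransferase gene Ugt1a2 (-6.40 ± 0.33) and the transporter gene Slc7a12 (-3.93 ± 0.55). In all, 7.94% of tested autosomal genes differed with the pattern.

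The day 5 difference had a different size in different lists, which were not shown to be unequal. The day 5 difference against the direction of obstruction, as a share of the mean response, was 48.9 ± 23.1% (SE) for neutrophil, 28 ± 29.9% for urothelial, 27.4 ± 14.4% for interferon-stimulated, 24.9 ± 11.3% for cell cycle, 23.4 ± 8.67% for proximal tubule and 21.9 ± 5.58% for fatty acid oxidation genes. It was 3.6 ± 8.41% for matrix and 1.82 ± 7.05% for macrophage genes. This share takes no account of day 0: the response itself had a larger mean in knockout for immediate early (1.25 against 0.94), antioxidant (-0.75 against -0.69) and matrix genes (2.52 against 2.50). Erythroid genes such as Hbb-bt (-2.51 ± 0.78 log2 units) and Alas2 (-2.31 ± 0.76) and the brown adipocyte gene Ucp1 (-1.90 ± 0.75) were lower in knockout at day 5, none past the threshold (adjusted p = 0.765, 0.799 and 0.854). Without wild type day 5 replicate 1, Hbb-bt was -1.41 and Alas2 -1.23, so blood in that kidney may contribute to the erythroid difference, which was not tested further.

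A hypothesis from these data is that loss of Sprr2f may lessen tubular identity loss and neutrophil entry more than the rise of matrix genes. It rests on lists that do not pass with an estimated correlation (0 of 37) and on neutrophil values that overlap between genotypes. The interval of the proximal tubule to matrix difference (19.8 percentage points) includes 0. The hypothesis does not extend to scarring as a whole. Myofibroblast and TGF-beta genes were also lower in knockout at day 5 at the fixed correlation (adjusted p = 0.0140 and 0.000896). The neutrophil list did not pass the interaction test at that correlation (adjusted p = 0.0834). With the sex-pattern covariate, proximal tubule and matrix genes also differed before obstruction (adjusted p = 0.0399 and 0.00468), which the hypothesis does not explain. A test of it would need kidneys of 1 sex, matched for time of collection, with at least as many animals per group.

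For obstruction in knockout, chance was excluded for the genes: the real split called 9917 and the highest of the other 34 splits of the 7 libraries 4156 (1 of 35 gave as many). For the lists the count cannot decide (22, highest other 25, 8 of 35 gave as many). Mixed splits still hold unequal shares of obstructed kidneys. With the sex-pattern covariate the responses of both genotypes correlated with r = 0.931.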
